A study of Populus trichocarpa with 2 samples.

How the data were processed

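The series holds droplet-based single-nucleus RNA sequencing (10x Genomics Chromium) of stem tissue of Populus trichocarpa, black cottonwood, a poplar. The 2 libraries, replicate 1 and replicate 2, form 1 group, the stem. Per the labels' protocols, rooted cuttings grew for 6 weeks in a greenhouse at 5 mM nitrogen, the entire stem was taken at leaf plastochron index 4 to 5, an index of leaf age along the shoot, and 20k nuclei were loaded per library. Reads were 28 bases for barcode and molecular identifier and 90 bases for cDNA.

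The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, written by Cell Ranger per the file headers. The submitters' processing notes name Cell Ranger 5.0 and 3.1.0 without giving a role to either. The genome build, the annotation, the rule that selected barcodes and the handling of reads that map to several genes are not given in the sources used here, so close paralogs could share UMIs. The files hold 34699 gene IDs. No cell type annotation by the authors was used here.

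Library 1 held 10881 barcodes with 35043980 UMIs and library 2 held 16880 barcodes with 40933645 UMIs. The median barcode held 1712 UMIs in library 1 and 940 in library 2. A minimum of 500 UMIs removed no barcode, since the lowest held 555 and 656. Scrublet, at an expected doublet rate of 0.08, called 1 barcode in library 1 and 0 in library 2. These calls lie far under the expected rate, so doublets were probably missed, though its performance was not tested. The called barcode was left out and doublets otherwise remain.

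Clusters were built with Scanpy 1.11.5, igraph 0.11.9 and leidenalg 0.10.2 under Python 3.11.15. Counts were scaled to 10000 per barcode and log-transformed. The 3000 most variable genes were taken from genes seen in at least 10 barcodes of each library, leaving out every gene of the fixed lists. They were scaled within each library, and 30 principal components, 15 neighbours and a Leiden resolution of 0.8 gave 26 clusters. A cluster received a name when at least 3 genes of a marker list held 10 or more UMIs in it and a share of at least 0.5 of the list lay at a log2 ratio of 1 or more above the rest in each library. The marker genes were fixed before the data were examined, as were the gene lists, the tests and most of the other settings. The naming threshold was set afterwards, when list medians per cluster had been seen. The secondary wall list had 5 measured markers, the vessel element list 7, the cambium list 8 and the photosynthetic parenchyma list 2. The last list could not reach the minimum of 3 markers, and no cluster bears its name. Marker lists of phloem, epidermis, guard cells, periderm, stele, S phase and mitosis were fixed as product names and could not be used here.

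Gene IDs are printed as the files give them. The reference gene table matched 0 of the 34699 IDs, and the files do not pair IDs with gene names. Membership of a list therefore comes from knowledge of published poplar gene families, and no name is attached to any single ID. The 2 lists that could be tested were monolignol biosynthesis, with 22 IDs of which 21 passed the count filter, and wall NAC and MYB regulators, with 8 IDs. The planned test of a general transcription factor list needed product names and was not run. Lists of 17 flavonoid, 4 xylan synthase, 12 primary wall cellulose synthase, 35 laccase and 5 sucrose genes were added after the data were seen, and were tested in clusters built without them.

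UMIs were summed per library over all nuclei of a named class or of an unnamed cluster with at least 20 nuclei in each library, which gave 21 units and 42 sums. Cluster 26 fell short of that minimum. Sums were tested with edgeR 4.0.16 (TMM normalization, quasi-likelihood test) under R 4.3.3, with the library as a block and 20 residual degrees of freedom. Each class was set against the unweighted mean of all other units on the log scale, and the vessel element-like class also against the secondary wall-forming-like class. Of the genes, 23518 passed the filter on low counts. P-values were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05, and also over each list alone. A fitted fold change depends on the prior count where units hold no UMI of a gene, so values within each library, on log2 CPM with a prior count of 2, are given beside it where they differ. Lists were tested with limma 3.58.1 (camera, preset correlation 0.01, adjusted over 8 tests), with an estimated correlation and fry as alternatives. Summed CPM is the share of all UMIs of a unit that fell on a list, on the CPM scale. Shares of barcodes have exact (Clopper-Pearson) 95% intervals, which cover counting error only.

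The block is the library itself, since all units of a library share its nuclei preparation. Leaving out a library left no residual degrees of freedom between libraries, so those values have no test. No test was made between the libraries.

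Genes were named by a rule: per class and list, up to 3 members with the highest and 1 with the lowest fold change among those past the threshold, with the same sign in each library and at least 10 UMIs. At most 2 IDs that rose and 2 that fell are printed per comparison. The test was tried on simulated sums, with 200 genes changed. For the secondary wall-forming-like class, on 21601 genes, it recovered 90% of 2-fold and 97% of 4-fold changes. For the cambium-like class, on 21587 genes, it recovered 93.9% and 99%. For the vessel element-like class, on 21589 genes, it recovered 7% and 43%. False calls made up 8.78%, 8.13% and 5.66% of all calls in that order.

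Other settings fixed before the data were examined were DESeq2 1.42.0 size factors, its Wald test, no filter on low counts, no block, each library alone, count splitting, resolutions of 0.4 and 1.2, a minimum of 1000 UMIs, doublets kept, joint scaling and clustering with the list genes. Added after the data were seen were the removal of the highest Scrublet scores, clustering without the added lists, each cluster as its own unit, a reference without cluster 1, shares outside cluster 1, and the vessel element-like class without barcodes above 3000 UMIs. Values under other settings were called the same on direction and side of the threshold, and a count could change up to 1.5-fold. With 2 libraries, each lies within the SD of their mean, so values of each library alone do not test size.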

Results

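Nuclear RNA of the poplar stem was profiled in 2 libraries of 1 group, so the comparisons lie between cell classes within the stem and not between conditions. They address which cell types of the stem carry the transcripts of lignin synthesis and of its regulators. The files hold 10881 barcodes and 35043980 UMIs in library 1, and 16880 barcodes and 40933645 UMIs in library 2. Of these barcodes, 35.9% in library 1 and 53.4% in library 2 held under 1000 UMIs. The labels do not say that the libraries came from separate plants, so the spread behind the p-values may be technical. With the library as a block, that spread is how far differences between units varied between the 2 libraries. It is pooled over all 21 units and is not that of a single class. Summed over all barcodes, log2 CPM of the libraries correlated across 24465 genes with a Pearson coefficient of 0.984 and a Spearman coefficient of 0.985. Genes are not independent replicates in that value.

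Of the 26 clusters, 7 carried the markers of a cell type. Cambium-like nuclei, from clusters 4 and 8, carried markers of the dividing layer that gives rise to wood and phloem. Cluster 4 passed with 4 of 8 markers, the least that the threshold allows, and cluster 8 with 6. The marker Potri.002G113300 was lower in the class than in the other barcodes, at 253 against 343 CPM in library 1 and 225 against 297 CPM in library 2. The class made up 9.41% of library 1 (95% interval 8.87 to 9.98) and 6.69% of library 2 (6.32 to 7.08), a mean of 8.05% ± 1.92 (SD, n = 2). Secondary wall-forming-like nuclei, from clusters 6, 11, 18 and 19, carried cellulose synthase markers of the secondary wall and made up 10.1% (9.57 to 10.7) and 8.40% (7.99 to 8.83), a mean of 9.26% ± 1.22. Vessel element-like nuclei, from cluster 25, carried markers of the water-conducting cells that die at maturity. They numbered 40 in each library, 0.368% (0.263 to 0.5003) and 0.237% (0.169 to 0.323), a mean of 0.302% ± 0.0924.

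Cluster 1 bore no name, took 30.7% of library 1 and 50.5% of library 2, and held a median of 712 and 757 UMIs per barcode. Outside cluster 1, cambium-like nuclei made up 13.6% ± 0.0290 of barcodes, secondary wall-forming-like nuclei 15.8% ± 1.68 and vessel element-like nuclei 0.505% ± 0.0362. Clusters 5 and 17 fell short of the cambium threshold with 2 and 3 of 8 markers. Cluster 5 held 5.15% and 3.79% of the libraries and cluster 17 held 1.78% and 1.45%. After centring each gene over the 21 units, 19 units of library 1 correlated best with the same unit of library 2. The lowest correlation of a unit with itself was 0.172, for cluster 20. Clusters were built from both libraries together, so such a match is partly built in.

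**Figure D1:**
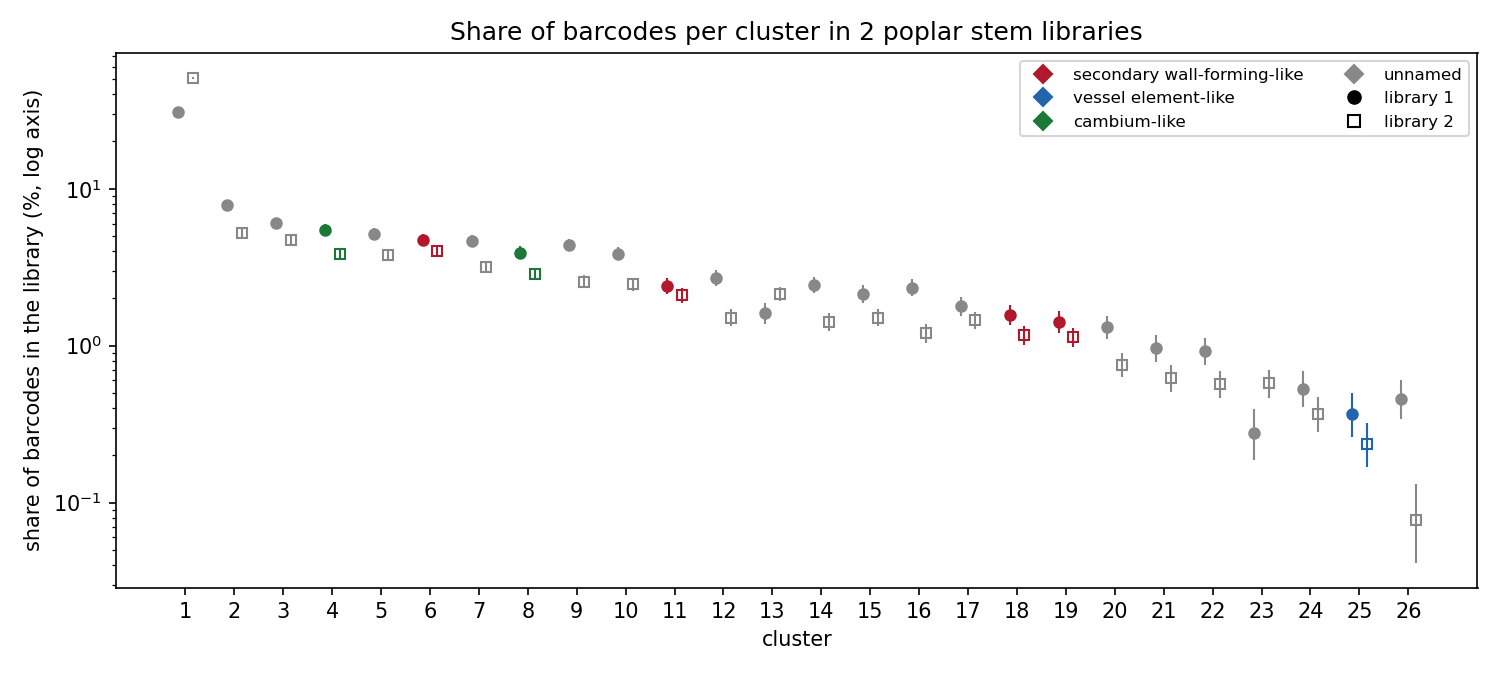
Share of barcodes (%, log axis) in each of the 26 clusters, with filled points for library 1, open points for library 2, exact 95% binomial intervals as bars and colours for the named classes. Cluster 1 took 30.7% and 50.5% of the libraries, and the vessel element-like cluster 25 took 0.368% and 0.237%.

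In secondary wall-forming-like nuclei, both the genes of lignin building blocks and the transcription factors that control the secondary wall were higher than in the mean of the other units. All 21 tested members of the monolignol list rose, by log2 fold changes of 1.77 to 4.11 with a median of 2.87. All 8 wall NAC and MYB regulators, which are known to switch on secondary wall genes, rose by 2.11 to 5.28 with a median of 3.82. Adjusted over the list alone, the counts were again 21 and 8. Monolignol transcripts summed to 17913 ± 1179 CPM in this class (SD, n = 2) and regulators to 790 ± 47.3 CPM. In cluster 1 the lists summed to 7081 ± 877 and 149 ± 26.3 CPM. Most regulator UMIs of the class came from cluster 18, with 1971 of 2601 in library 1 and 3117 of 4200 in library 2, and clusters 6, 11 and 19 lay at 304, 282 and 129 CPM.

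The monolignol gene with the largest fitted fold change in this class, Potri.010G224100, reached 2170 ± 46.7 CPM against 188 ± 10.6 CPM in the mean of the other units. Its log2 fold change was 4.11 (SE 0.0785, adjusted p = 2.72e-48, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The regulator with the largest fitted fold change, Potri.009G061500, lay at a low level, 19.8 ± 7.07 CPM against 1.60 ± 0.410 CPM. Its fitted log2 fold change was 5.28 (SE 0.365), and within the libraries it was 3.78 and 2.88, where 4 other regulators had larger values in both. As sets, the monolignol list (camera, adjusted p = 1.91e-45) and the regulators (adjusted p = 5.49e-08) were higher than the other tested genes. With an estimated correlation, the adjusted p was 1.78e-07 and 0.00787. Across all 23518 tested genes, 6317 were higher and 3606 lower in this class. Of its 4 clusters, cluster 19 taken alone had 8 of 21 monolignol genes higher and 1 of 8 regulators, and cluster 11 had 4 of 8 regulators higher.

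**Figure D2:**
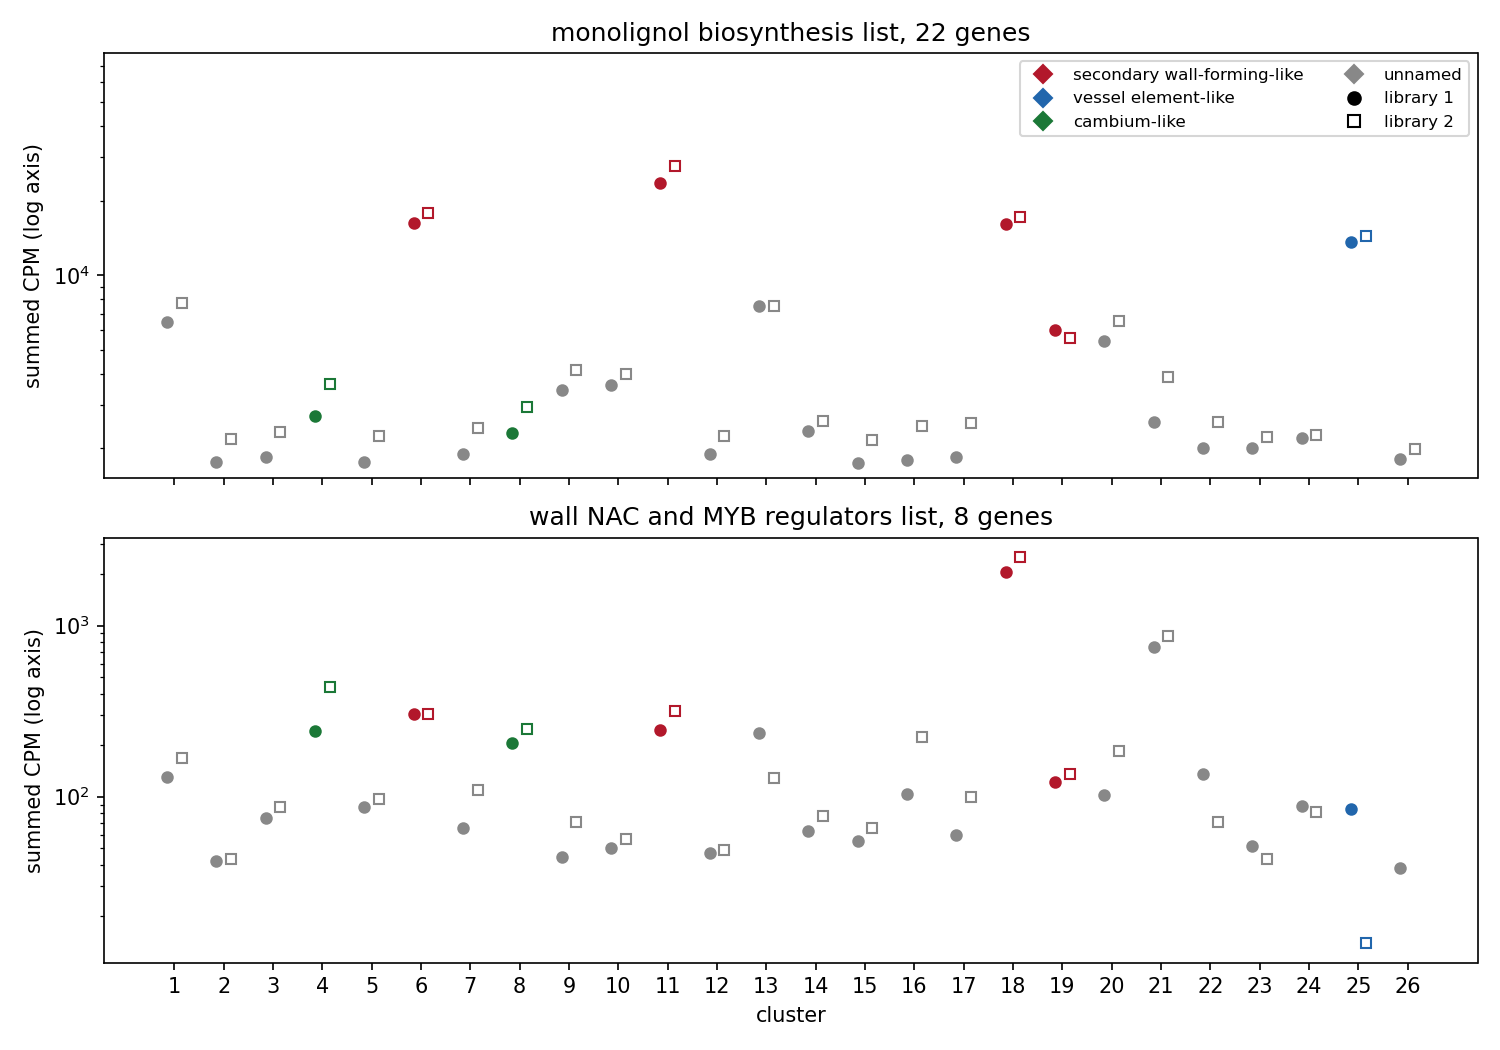
Summed CPM (log axis) of the monolignol list of 22 genes and the wall regulator list of 8 genes in each cluster, with filled points for library 1, open points for library 2 and no point for a sum of 0. Secondary wall-forming-like clusters 6, 11, 18 and 19 lie at 16982, 25543, 16637 and 5784 CPM in the monolignol panel, as means of both libraries, and unnamed clusters 1, 13 and 20 lie above cluster 19.

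In the vessel element-like class, most monolignol genes were higher than in the mean of the other units, while none of the 8 wall regulators tested passed. NAC genes of the vessel type were planned as naming markers of this class. No naming marker is among the 8, so the result covers this list only. Of the 21 monolignol genes, 19 rose, and 20 adjusted over the list alone, with a median log2 fold change of 2.24 where all tested genes had a median of −0.71. The list summed to 13993 ± 590 CPM (SD, n = 2), against 7081 ± 877 CPM in cluster 1. For 67 of the 80 barcodes, free RNA and own transcripts cannot be told apart. Potri.008G038200 lay at 1239 ± 243 CPM against 181 ± 12.5 CPM in the other units, a log2 fold change of 3.63 (SE 0.198, edgeR adjusted p = 1.18e-23). Potri.003G188500 had the highest fitted value, 5.36 (SE 0.286), with 1557 CPM in library 1 and 279 CPM in library 2. As a set the monolignol list was higher (camera, adjusted p = 9.52e-26, and 8.02e-06 with an estimated correlation).

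For the wall regulators in vessel element-like nuclei, 0 of 8 passed in either direction with edgeR or DESeq2, and 0 had an unadjusted p under 0.05 with either tool. The 8 genes together held 9 UMIs in library 1 and 1 UMI in library 2, and the set test gave an adjusted p of 0.734. With fry, which does not set the list against other genes, it was lower (adjusted p = 0.00171), where all tested genes had a median log2 fold change of −0.71. The deepest barcode held 22.4% of the UMIs of this class in library 1 and 12.99% in library 2. In library 1, 8 barcodes above 3000 UMIs held 70501 of the 105774 UMIs of the class. In library 2, 5 such barcodes held 33270 of 71894. Across genes the class sums of the libraries correlated at 0.323 (Pearson). Without the 13 barcodes above 3000 UMIs, a step added after the data were seen, 10 of 21 monolignol genes rose, 15 adjusted over the list alone, with a median of 1.34.

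Set directly against the secondary wall-forming-like nuclei, vessel element-like nuclei had lower levels of several of the 8 wall regulators, while the set test of the monolignol list passed or not with the barcodes used. Of the 8 regulators, 4 were lower, and 6 adjusted over the list alone (camera, adjusted p = 0.00200, and adjusted p = 0.0931 with an estimated correlation). Potri.001G448400 had 2 UMIs in the vessel element-like class and 2999 in the other class. The ratio of its UMI shares was 0.0321 (exact 95% counting interval 0.00388 to 0.116). Of the 21 monolignol genes, 11 were lower, 1 was higher and 9 did not pass, with a median log2 difference of −0.75 where all tested genes had −0.76 (camera, adjusted p = 0.406). Across all 23518 tested genes, 1540 were lower and 802 higher. Potri.008G136600 was lower by a log2 difference of −3.74 (SE 0.325), from 13 UMIs against 7123. The 1 higher gene, Potri.003G188500, had a difference of 1.41, with 2.19 in library 1 and −0.42 in library 2. The count of lower monolignol genes was 6 with no replicate block and 18 without the barcodes above 3000 UMIs, where the set test gave an adjusted p of 0.00413.

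In cambium-like nuclei, most monolignol genes were lower than in the mean of the other units, which include the wall-forming classes, and 6 of 8 wall regulators were higher. Of all 23518 tested genes, 7143 were higher and 3851 lower in this class. Against the mean of the other units on the log scale, 13 of the 21 monolignol genes fell and 3 rose, and 14 and 3 adjusted over the list alone, with a median log2 fold change of −0.50 (camera, adjusted p = 3.23e-05, and 0.0291 with an estimated correlation). Potri.003G188500 fell most, by a log2 fold change of −1.20 (SE 0.229), to 12.5 ± 0.0460 CPM. The regulators had a median of 1.59, and the set test gave an adjusted p of 0.00200, or adjusted p = 0.0931 with an estimated correlation. At resolution 1.2, 4 regulators were higher, with a median of 0.48 and an adjusted p of 0.113, and at a minimum of 1000 UMIs 5 were higher, with a median of 0.50. Potri.009G061500 rose by 3.28 (SE 0.469), or by 1.57 and 1.51 within the libraries, to 5.11 ± 0.288 CPM, from 10.7 CPM in cluster 8 and 0.157 CPM in cluster 4. Regulators summed to 287 ± 86.3 CPM in this class, above 17 of the 18 unnamed units. The monolignol list summed to 2914 ± 554 CPM, above 12 and below 6 of the 18, cluster 1 among the 6. Of the 3 higher monolignol genes, led by Potri.003G181400 at 0.56 (SE 0.0917), only this one also had a higher mean CPM than the other units, 272 against 250. The others had a lower one, 108 against 130 and 111 against 114, so their direction rests on the log scale. The direction also changed with the clustering. Taken alone, cluster 4 had 3 monolignol genes and 4 of 8 regulators higher, and cluster 8 had 0 monolignol genes (0 at an unadjusted p under 0.05, edgeR) and 5 regulators. At resolution 1.2, 0 were higher and Potri.003G181400 lay at −0.34, and with joint scaling 1 was higher and it lay at −0.01.

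**Figure D3:**
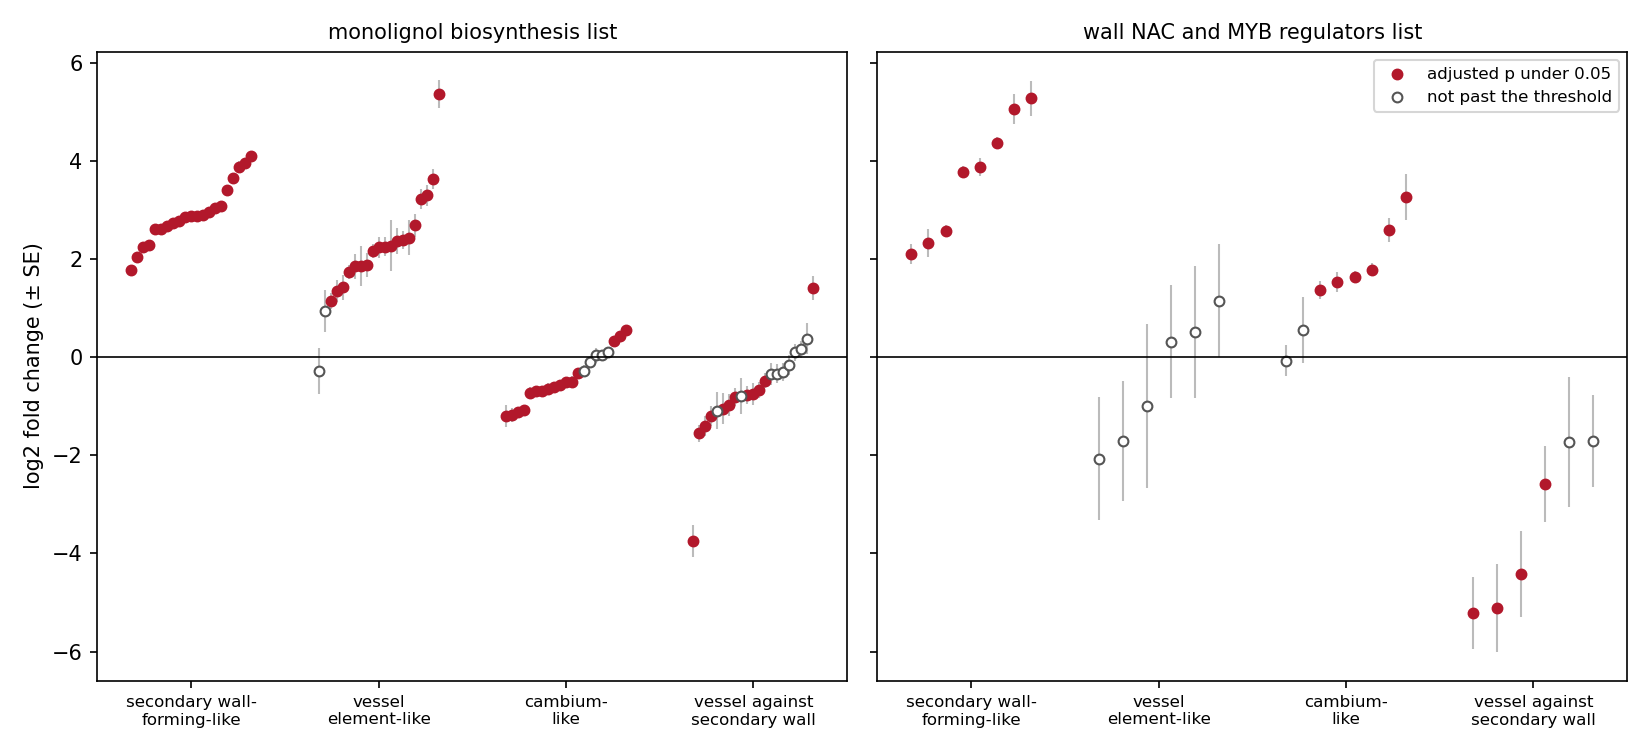
Log2 fold change with its standard error (bars) of each gene of the monolignol list and of the wall regulator list in the 4 comparisons, filled where the adjusted p was under 0.05 and open otherwise, without genes that had no UMI in the class. The regulators drawn for vessel element-like nuclei held 1 to 3 UMIs each there. In the secondary wall-forming-like class all 21 monolignol genes and all 8 regulators lie above 0, and in the vessel element-like class 19 monolignol genes passed as higher and 0 regulators did.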

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

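Of 291 values of counts, set tests and shares under other settings, 266 were called the same by rules that hardly test size. Those with doublets kept, 1 barcode apart, are included. Chosen after the data were seen were the steps on the highest Scrublet scores, the added lists, cluster 1 and the barcodes above 3000 UMIs. In the secondary wall-forming-like class, all 8 regulators and 21 or 22 monolignol genes were higher in each of 15 settings. The cause of the changes below was not tested.

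Without the vessel element-like barcodes above 3000 UMIs, 10 monolignol genes were higher in that class. Against the secondary wall-forming-like nuclei, 18 were lower and 0 higher with edgeR (0 at an unadjusted p under 0.05), and the list test gave an adjusted p of 0.00413. The set of regulators in that class turned to the higher direction without passing, at adjusted p = 0.657 there and 0.693 under count splitting. With no replicate block, 6 monolignol genes were lower than in the secondary wall-forming-like class. With fry, which asks whether a set moves at all, the regulators in the vessel element-like class (adjusted p = 0.00171) and the monolignol list against the secondary wall-forming-like class (3.75e-07) passed. With an estimated correlation, the regulators missed the threshold in the cambium-like class and between the vessel element-like and secondary wall-forming-like classes (adjusted p = 0.0931 for both). At resolution 1.2 they also missed it in the cambium-like class with the preset correlation (0.113).

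The count of monolignol genes higher in the cambium-like class was 0 at resolution 1.2, 1 with joint scaling and 1 when list genes entered the clustering. At resolution 1.2, Potri.003G181400 turned to −0.34 and a second gene of the list to −0.37. With joint scaling it lay at −0.0121 and the 2 others at −0.50 and −0.65. The cambium-like share was 5.66% at resolution 1.2, 3.49% with joint scaling, 12.1% at a minimum of 1000 UMIs and 13.6% outside cluster 1, where shallow barcodes leave the denominator. The secondary wall-forming-like share was 7.82% with joint scaling, 7.86% with list genes, 10.9% at 1000 UMIs and 15.8% outside cluster 1. The vessel element-like share was 0.199% at 1000 UMIs and 0.505% outside cluster 1.

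Each library alone gave list medians with the same sign as both. For monolignol genes they were 2.76 to 2.95 in the secondary wall-forming-like class, 1.87 to 2.34 in the vessel element-like class and −0.58 to −0.43 in the cambium-like class. At 1000 UMIs the vessel element-like class had under 20 nuclei in a library and gave no test. The minimum of 500 UMIs and the doublet call removed 0 and 1 barcodes, so neither tests stability. Simulated 4-fold changes were recovered least in the vessel element-like class, at 43%, a value that was not measured for the list genes alone.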

Other observations

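The 2 tests on cluster 1 were set before their results were seen. The tests on the vessel element-like class, on the split of the secondary wall-forming-like class and on the added lists, and the comparisons of single clusters, were chosen after the result was seen. Those on the vessel element-like class replaced an earlier ratio over all its barcodes, of 1.80 and 1.84 in the libraries, once the barcodes above 3000 UMIs had been found, and were then moved from the called genes to the whole list. The free RNA test of the split was changed from a gene pair to list sums.

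The clusters of the secondary wall-forming-like class differed in how much regulator and monolignol transcript they carried. Cluster 18 held 2278 ± 324 CPM of wall regulators and 16637 ± 828 CPM of monolignol transcripts (SD, n = 2), and cluster 11 held 282 ± 51.5 and 25543 ± 2715 CPM. Compared directly in edgeR, all 8 regulators were higher in cluster 18 than in cluster 11, with a median log2 difference of 3.35, while 11 monolignol genes were lower and 3 higher. Cluster 11 in turn had 13 monolignol genes higher and 2 lower than cluster 6, with 3 regulators lower. Cluster 19 had 8 regulators and 14 monolignol genes lower than cluster 18, and 4 and 19 lower than cluster 6. Against cluster 11 it had 3 regulators lower and 5 not passing, with 19 monolignol genes lower and 1 higher. Cluster 18 had 6 regulators higher than cluster 6, with 7 monolignol genes higher and 6 lower. Outside the named classes, cluster 21 had 5 of 8 regulators higher than the other clusters, at a sum of 805 ± 83.7 CPM, with 5 monolignol genes lower. Between the cambium-like clusters, 10 monolignol genes were lower and 1 was higher in cluster 8 than in cluster 4, with 3 regulators lower and 2 higher. Potri.009G061500 was higher in cluster 8, with 60 UMIs against 1 in cluster 4.

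In the secondary wall-forming-like class, xylan synthase genes, which build the main hemicellulose of wood, passed as higher for 4 of 4 members (median log2 fold change 4.31). Laccase genes, known for joining monolignols into lignin, passed for 16 of 18 (median 3.76), and sucrose transport and cleavage genes for 3 of 4. Of 12 primary wall cellulose synthase genes, 5 were higher and 1 lower in this class, and 7 were higher and 4 lower in the cambium-like class. Of 10 flavonoid and tannin genes, 2 were higher and 1 lower. In the vessel element-like class, 4 of 4 xylan synthase and 7 of 18 laccase genes were higher. Against the secondary wall-forming-like nuclei, all 4 xylan synthase genes (median log2 difference −1.84) and 3 sucrose genes were lower in it. There 11 laccase genes were lower and 4 higher, led by Potri.007G023300 at 1075 ± 636 CPM in the vessel element-like class (256-fold, SE of the log2 difference 0.367), a gene chosen after its values were seen.

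Cluster 1 held few UMIs per barcode and took 30.7% of library 1 and 50.5% of library 2, and free RNA alone would give all its barcodes 1 profile and a dispersion index near 1 for the secondary wall, cambium and monolignol sets. The deciding index was 1.29, between the limits set in advance, so droplets of free RNA and nuclei cannot be told apart there. The excess of the index, as the median of the sets in the lower library, was 0.0764 of that of all other nuclei thinned to the same depth, and 0.0817 in the other library. Both medians lay under the limit set in advance against a low-depth mixture of the types in the other clusters, although the cambium set alone gave 0.361 and 0.249. Clustering gathers alike barcodes, which lowers the index within any cluster. Within single other clusters the ratio had medians of 0.069 and 0.0915 for the secondary wall set. It had medians of 0.154 and 0.153 for monolignol genes, and of 0.323 and 0.274 for the cambium set. The comparison therefore cannot decide between such a mixture and 1 type at low depth. No biological explanation was tested.

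Monolignol genes were higher in the vessel element-like class although most of its barcodes were shallow. In its 13 barcodes above 3000 UMIs, the 21 tested genes of the list lay at a median of 2.28 times the CPM of cluster 1 in library 1. In library 2 the median was 1.61 times. Both values argue against free RNA of that profile as the whole source and leave another profile open. In its 67 other barcodes the median was 1.27 in library 1 and 1.52 in library 2, where it lay close to that of the deep barcodes. Free RNA and own transcripts cannot be told apart in the 67, because the value of library 1 lies between the limits. Had doublets with a secondary wall-forming-like nucleus brought all monolignol UMIs of the deep barcodes, at least 17.4 regulator UMIs would be expected from average cluster profiles. The 4 seen, 0.230 of that number with an upper 95% Poisson bound of 10.2, argue against doublets as the whole source. That bound treats UMIs as independent, though they come from 13 barcodes. Doublets as a part of the source, and doublets among the shallow barcodes, stay open.

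Regulators and monolignol genes moved apart between clusters 18 and 11. The ratio of regulators to monolignol genes differed by a log2 value of 3.62 in the lower library, a value that restates the sums of these clusters. Free RNA of a single profile keeps its genes in 1 ratio, so this difference argues against free RNA as the whole cause. Among nuclei of 2500 to 5000 UMIs the summed regulators were still 10.7-fold higher in cluster 18 in the lower library, which argues against depth for the regulators. The summed monolignol genes there lay at 0.764 and 0.811 times those of cluster 11 in libraries 1 and 2. Whether a part of the monolignol difference follows depth was not tested. Doublets were not weighed here, the pair was chosen after its values were seen, and no biological explanation was tested.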
